A study of Mus musculus with 2 samples.

How the data were processed

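Thy1.1+ CD8+ P14 T cells were sorted from the livers of young and old recipient mice, and 1 single-cell library per recipient age was sequenced from a pool of 7 mice. Per the labels' protocols, libraries were made with a 10x Genomics 3' gene expression kit and sequenced on an Element AVITI instrument. The deposited matrices hold UMI counts per gene and barcode, made by the authors with Cell Ranger 8.0.1 against the build named mm10, per the submitters' processing notes. The deposited barcode and gene lists give the other labels needed to read those counts, with the gene symbols used here. Of 33696 gene identifiers, 31961 were found in GENCODE M21 and 1735 were not, so the annotation behind the counts is not that of M21. Because the annotation was unsure, no coordinates are given. The annotation release is not given in the sources used here. All cells of a library came from 1 pool, with no map from cells to mice used here.

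The computed quantities started from the UMI counts. Cells were kept with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs. This left 4066 of 4255 young-recipient barcodes and 5196 of 5443 old-recipient barcodes. Scrublet, run per library, called 2 and 0 doublets, so few that it is taken not to have worked, and doublets were therefore not removed in effect. An alternative without the cells above the 95th percentile of UMIs of their library was added after the data were seen. The gate asked for at least 1 UMI of Cd8a or Cd8b1 and at least 1 of Cd3e, Cd3d or Cd3g, and left out 154 and 207 cells. It left 43791201 and 46694041 UMIs. At these depths, 3 counts, the limit that a count of 0 allows, correspond to 0.0685 and 0.0642 CPM.

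UMIs were summed per library over gated cells and scaled to CPM, which set each gene's UMIs against all UMIs of its library. A gene was measured when its mean over the 2 libraries was at least 5 CPM. The log2 ratio is that of old-recipient over young-recipient CPM with a pseudocount of 1 CPM, which understates differences of low genes, and folds are ratios of CPM without it. Counts of genes at least 1.5-fold apart use the log2 ratio with the pseudocount, at a size of 0.585. CPM have exact Poisson intervals, folds exact conditional intervals and shares Clopper-Pearson intervals, all at 95% and for counting error only. With 1 library per group no p-value, standard error or test was computed. For each of 39 gene lists fixed before the data were examined, the median log2 ratio of the measured members was set among 10000 random lists of the same size matched on mean CPM in 20 bins. The percentile describes these libraries and is not a test, and lists with under 3 measured members have no percentile. The counting interval of a list median came from 2000 Poisson redraws of its members' counts, and that of a value in the tests of the closing section from 500. For 8 older symbols in the lists the current symbol was found through the gene identifier in M21.

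Named genes followed a rule fixed before the data were examined. It took the 10 highest and 10 lowest log2 ratios among genes with a mean of at least 20 CPM, leaving out predicted genes, antigen receptor and immunoglobulin segments and mitochondrial genes. It always named 18 key genes, whatever their value, of which 1 is not reported here: Pdcd1, Tox, Tcf7, Il7r, Gzmb, Gzma, Gzmk, Prf1, Ifng, Tnf, Klrg1, Cxcr6, Lag3, Havcr2, Mki67, Cd44 and Cd69. It also took up to 2 members per direction of each list with the largest log2 ratio and a mean of at least 20 CPM. Cluster-leading genes, T cell receptor segments and genes given as levels of other cell types were named outside it, after their values were seen.

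Cells of both libraries were clustered together with scanpy 1.11.5 and igraph 0.11.9. Counts were scaled to 10000 UMIs per cell and log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5, without batch integration. T cell receptor V genes and sex-linked, mitochondrial and ribosomal genes were left out of the variable genes. The 10 leading genes of a cluster had at least 50 CPM in it. Large clusters were those with at least 90 cells in each library. Clusters whose cycling markers had a median log2 fold above 0.5 over the other cells were called cycling-like, a threshold set after the data were seen. A second clustering left out 265 genes, as the report describes. For the shares of cells with a UMI, each cell was thinned to 4000 UMIs without replacement, the 10th percentile of the shallower library rounded down. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, R 4.3.3 and edgeR 4.0.16, the last for the TMM alternative only.

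The per-gene and list steps were checked on simulated data before use. In a simulation of old against young recipients over 8610 genes, 100 of 100 genes simulated 2-fold higher and 100 of 100 simulated 2-fold lower were past the 1.5-fold size, with 0 of the other genes. Of 40 random lists without a difference, 2 lay outside the middle 95%. The simulation held counting error only, not variation between animals or libraries.

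Alternatives fixed before the data were examined were edgeR TMM factors, CPM without mitochondrial and ribosomal protein genes, a pseudocount of 5 CPM, a minimum mean of 20 CPM and no minimum. Others were no cell filter or gate, a mitochondrial maximum of 5%, Scrublet calls kept, no Cd8 and Cd3 gate, the mean of the cells' own CPM, thinned cells, equal cluster weights and no cycling-like clusters. For the cycling share, resolutions of 1.0 and 0.3, clustering without cell cycle genes and Scrublet calls kept were tried. For the shares with a UMI, no thinning and 2000 UMIs were tried. The alternatives without clusters 3, 8 and 9 and with differing genes left out of the clustering were added after the data were seen.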

Results

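Young P14 CD8+ T cells, whose receptor recognises the gp33 peptide of lymphocytic choriomeningitis virus, were compared after transfer into young and old mice whose hepatocytes expressed that antigen. Per the labels, the P14 cells were activated with the peptide in culture and injected 2 weeks after the hepatocyte-directed vector, and livers were taken 5 days later. Thy1.1+ CD8+ cells sorted from the pooled liver immune cells of 7 mice gave 1 single-cell RNA library per recipient age. The comparison asks how the age of the recipient bears on the transcriptome of T cells that were themselves young. The young-recipient library held 4255 barcodes with 44422124 UMIs, and the old-recipient library held 5443 barcodes with 47625391 UMIs. After cell filters and a gate on Cd8 and Cd3 transcripts, 3910 and 4989 cells remained. Gated cells had a median of 8557 UMIs (95% interval of the median 8399 to 8736) and 2471 genes in the young-recipient library, against 7359 UMIs (7219 to 7482) and 2241 genes in the old-recipient library. With 1 library per age there was no replicate check and no test, so every value compares these libraries and not the conditions. Intervals are exact 95% Poisson or Clopper-Pearson intervals and cover counting error only. Those of CPM and folds count UMIs and not cells, so they are too narrow for genes whose UMIs gather in few cells, such as Gzmb.

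The old-recipient library held more transcripts of granzymes, perforin and interferon response genes, and fewer of the cytokine genes Ltb and Xcl1. Gzmb (ENSMUSG00000015437), which encodes granzyme B of cytotoxic granules, stood at 10.6 CPM in the young-recipient library and 43.6 CPM in the old-recipient library, 4.12-fold higher (3.72 to 4.56), and its log2 ratio was 1.94, or 1.10 when each cell cluster was given equal weight in the 2 libraries. Irf7 (ENSMUSG00000025498), a transcription factor of the type I interferon response, was 2.31-fold higher (2.14 to 2.49), at 22.4 and 51.6 CPM. Ltb (ENSMUSG00000024399), which encodes lymphotoxin beta, stood at 161 CPM in the young-recipient library and 45.2 CPM in the old-recipient library, 3.56-fold lower (3.39 to 3.74). Xcl1 (ENSMUSG00000026573), a chemokine that attracts cross-presenting dendritic cells, was 2.19-fold lower (2.14 to 2.25), at 487 and 222 CPM. The exhaustion-associated transcription factor Tox was level between the libraries, at 867 CPM in each.

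Among 8612 measured genes, 93 were at least 1.5-fold higher and 59 at least 1.5-fold lower in the old-recipient library, a count by size and not a test. Here and below such counts use the log2 ratio with the pseudocount, so genes just past 1.5-fold in CPM can be left out. The 10 highest log2 ratios among well-measured genes belonged to Gzmb (1.94), Il10ra (1.28), Irf7 (1.17), Bcl3 (1.16), Kcnc1 (1.16), Setbp1 (1.03), Serpina3g (1.00), Klrh1 (0.99), Xaf1 (0.99) and Trerf1 (0.96). Il10ra, which encodes a chain of the interleukin-10 receptor, stood at 21.7 and 54.1 CPM in young and old recipients. Under the alternatives that lowered them most, Il10ra fell to 0.761 and Kcnc1 to 0.593. Both lead cluster 0, described below, inside which their log2 ratios were 0.306 and 0.307. The 10 lowest belonged to Ltb (-1.81), Xcl1 (-1.13), Prmt1 (-0.98), Metrn (-0.79), Rpl9 (-0.77), Tuba1b (-0.77), Cd226 (-0.76), Nfkbil1 (-0.74), Bax (-0.74) and Nrgn (-0.73). Cd226, a co-stimulatory receptor, stood at 61.2 CPM in the young-recipient library and 35.7 CPM in the old-recipient library, and Bax, a pro-apoptotic BCL-2 family member, at 45.1 and 26.6 CPM. The median log2 ratio over all measured genes was -0.011. These counts depended on how low genes were treated: with a mean of at least 20 CPM, 42 and 21 genes lay past the same size, and without a filter on low values 197 and 108.

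**Figure D1:**
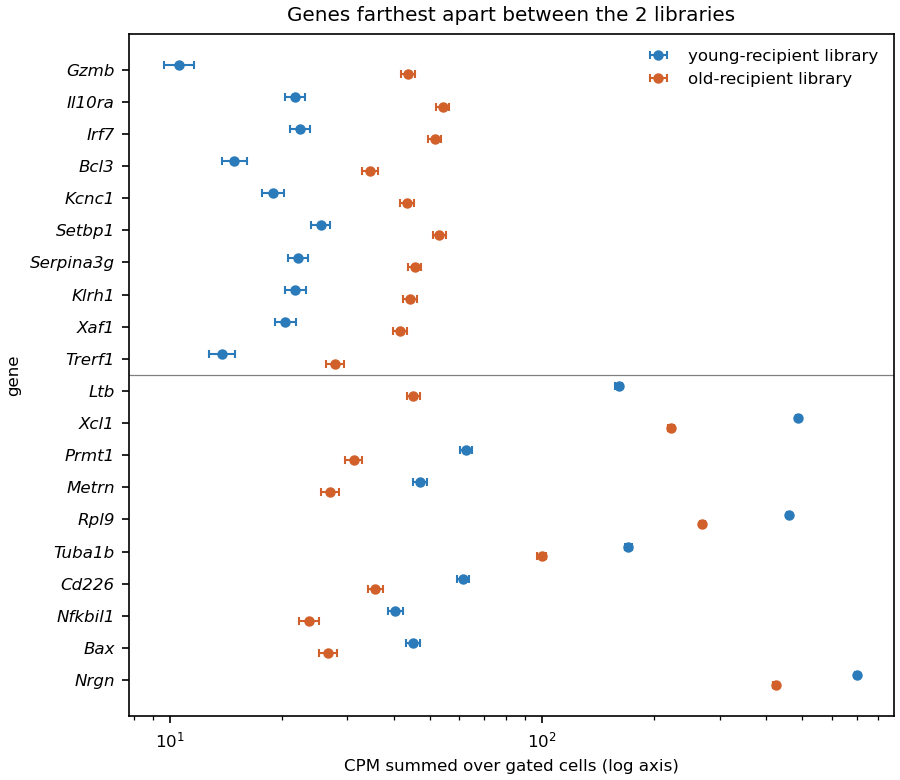
CPM summed over gated cells (log axis) of the 10 genes with the highest and the 10 with the lowest log2 ratio, for the young-recipient library (blue) and the old-recipient library (orange); bars are exact 95% Poisson intervals. Gzmb lies at 10.6 and 43.6 CPM at the top, and Ltb at 161 and 45.2 CPM is the lowest ratio.

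Granzyme and perforin genes were higher in the old-recipient library. Here and below, examples from a list had a mean of at least 20 CPM, apart from key genes and markers of other cell types, so rarer members can lie farther apart. Of 17 measured genes of the cytotoxic granule and killing list, 14 were higher and 3 lower, and 6 were at least 1.5-fold higher. Besides Gzmb, Gzmk stood at 2.37 and 11.2 CPM, Gzma at 6.85 and 16.7 CPM, and Prf1, which encodes perforin, at 51.9 and 96.8 CPM in young and old recipients. Srgn and Serpinb6b had log2 ratios of -0.12 and -0.060. The list median was 0.23 on the log2 scale (counting interval 0.11 to 0.33), at percentile 100 of 10000 random lists matched on mean expression. This median lay at 0.071 when each cell cluster was given equal weight in the 2 libraries, and at 0.083 over genes with a mean of at least 20 CPM. Gzma and the chemokine gene Ccl5 changed sign under equal cluster weights, with log2 ratios of -0.274 and -0.345, and Gzmk went from 1.85 to 1.25, or 1.14 with a pseudocount of 5 CPM. Within the 7 large clusters, Gzma, at low levels in most, was higher in old recipients in 6 and Ccl5 in 5. Both were lower in the granzyme-high cluster described below, which held only 97 young-recipient cells. Their values under equal cluster weights rest largely on those cells. In the same library, markers of monocytes and dendritic cells were also higher (median 0.83 over 3 measured genes, percentile 100), through Cd74 (3.81 and 9.04 CPM) and the interferon-responsive Bst2 (5.37 and 10.3 CPM), while Cst3 was level.

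Interferon response genes were higher in the old-recipient library, and their list medians lay above 0 in every large cluster of cells. Of 29 measured type I interferon response genes, 28 were higher and 1 was lower, with 13 at least 1.5-fold higher. Xaf1 stood at 20.4 CPM in the young-recipient library and 41.6 CPM in the old-recipient library. Ifi209 was the exception, at 58.7 and 54.5 CPM. The list median was 0.49 (0.48 to 0.59), at percentile 100. Of 27 measured genes of the interferon gamma response and antigen presentation list, 24 were higher and 3 lower. With the pseudocount 8 were at least 1.5-fold higher, and the median was 0.42 (0.31 to 0.49, percentile 100). Iigp1, an interferon-induced GTPase, stood at 15.2 and 29.5 CPM and the transcription factor Irf1 at 77.0 and 134 CPM, whereas B2m (-0.11) and Tap2 (-0.051) were slightly lower. Within the 7 large clusters, the type I list median ran from 0.12 to 0.62 and the gamma list median from 0.056 to 0.56. Both were lowest in cluster 1, and no random lists were set beside the cluster medians. Without the low-depth, granzyme-high and myeloid-marker clusters, the type I median was 0.31 and the gamma median 0.18. Monocyte and dendritic cell markers, which share Bst2 with the type I list, were higher in the same library, as given above.

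**Figure D2:**
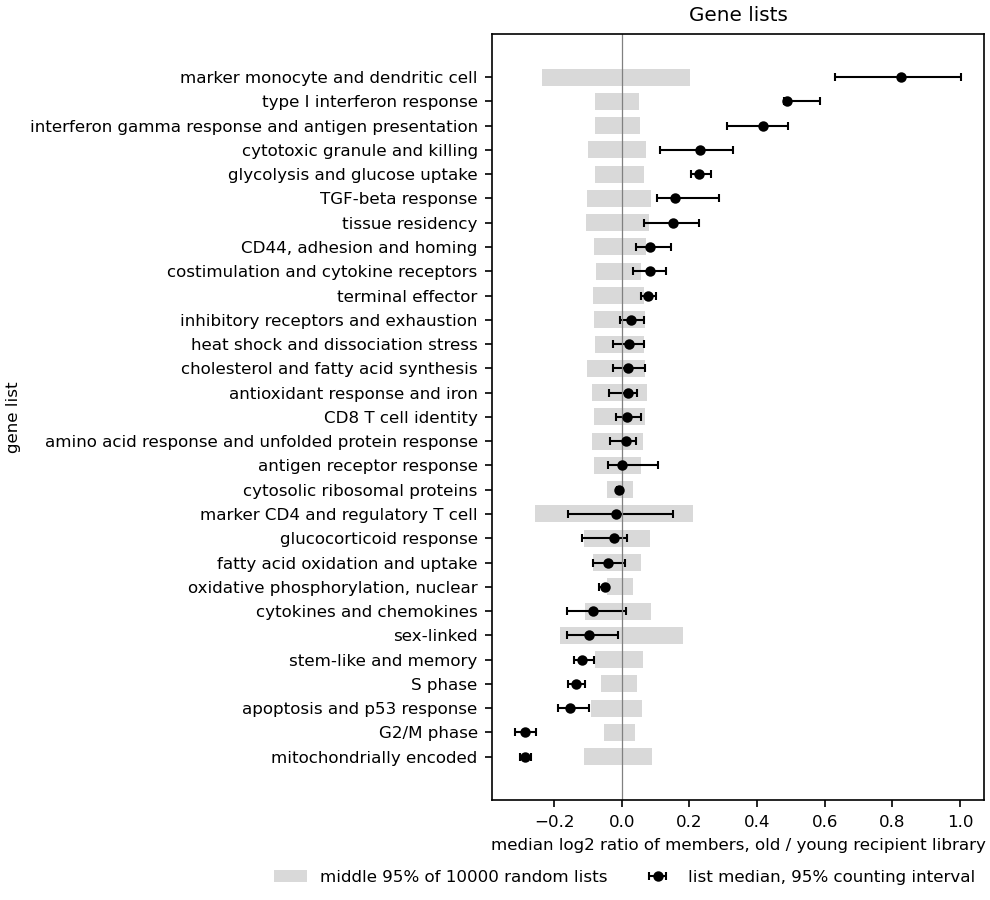
Median log2 ratio (old-recipient over young-recipient library) of the measured members of each gene list with at least 3 of them; whiskers are 95% counting intervals and grey bars the middle 95% of 10000 random lists matched on mean expression. The type I interferon list lies at 0.49 and the G2/M list at -0.28, both outside their grey bars, and the exhaustion list at 0.027 lies inside.

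Stem-like and memory genes were slightly lower in the old-recipient library. The median of the inhibitory receptor and exhaustion list had no direction that held across alternatives. Single members did: Pdcd1, Nt5e and Cd200 stayed lower, and Lag3, Cd7 and Havcr2 higher, under all 13 alternatives. Of 22 measured stem-like and memory genes, 14 were lower and 8 higher, with a median of -0.12 (percentile 0.14). This median was not lower in every large cluster: it ran from -0.23 in cluster 0 to 0.117 in cluster 8, with 0.004 in cluster 1. Ltb and Dapl1 (696 and 442 CPM) were lowest, and S1pr1 (97.7 and 121 CPM) and Satb1 (40.9 and 47.8 CPM) were higher. The naive and memory T cell regulator Tcf7 stood at 635 and 594 CPM, and the interleukin-7 receptor gene Il7r at 17.90 and 13.04 CPM. The inhibitory receptor and exhaustion list had 12 of 21 genes higher and a median of 0.027 (percentile 81.8), which ran from -0.11 without cycling-like clusters to 0.12 with no filter on low values. In it, Pdcd1, which encodes PD-1, stood at 42.6 CPM in the young-recipient library and 37.9 CPM in the old-recipient library, and Lag3 at 300.4 and 337 CPM. Cd7 (18.2 and 26.9 CPM) and Eomes (110.0 and 139 CPM) were higher, with Eomes at -0.078 on the log2 scale under equal cluster weights, and Nt5e (43.8 and 31.2 CPM) and Cd200 (472 and 344 CPM) were lower. Havcr2, which encodes TIM-3, was rare, at 1.92 and 5.42 CPM, as were Klrg1 (0.82 and 1.46 CPM) and Cxcr6 (1.53 and 3.49 CPM), and their log2 ratios of 1.14, 0.43 and 0.83 became 0.21, -0.495 and 0.067 under equal cluster weights. Those weighted values rest largely on the 97 young-recipient cells of the granzyme-high cluster described below.

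Cytokine genes went both ways. Of 12 measured cytokine and chemokine genes, 5 were higher and 7 lower (median -0.086, percentile 6.02). Ccl5 stood at 187 and 337 CPM and Ccl4 at 58.1 and 67.2 CPM in young and old recipients, Ifng at 6.26 and 7.60 CPM, and Tnf at 14.2 and 12.2 CPM. Ccl4 kept its sign under 7 of 13 alternatives, down to a log2 ratio of -0.199 with equal cluster weights, and Ifng under 11, down to -0.017 with the mean of the cells' own CPM. The terminal effector list had 15 of 20 genes higher (median 0.076, percentile 98.9), with Ifngr1 at 0.59 and Tbx21 at 0.36 on the log2 scale, and S100a10 at -0.27 and S1pr4 at -0.14. Its median lay at -0.009 under equal cluster weights. In the tissue residency list 8 of 14 genes were higher (median 0.15, percentile 99.9), with Fos (0.59) and Skil (0.41) above and Xcl1 and Inpp4b (-0.25) below, and a median of 0.017 in thinned cells. Costimulation and cytokine receptor genes had a median of 0.083 (15 of 25 higher, percentile 99.7), with Il10ra and Slamf7 (0.61) above and Cd226 and Il18r1 (-0.56) below, and this median was near 0 under equal cluster weights, with -0.002. TGF-beta response genes had a median of 0.16 (12 of 15 higher, percentile 99.97), with Skil and Junb (0.32) above and Xcl1 and Id3 (-0.20) below. The CD44, adhesion and homing list had a median of 0.084 (11 of 19 higher, percentile 99). In it Cd44, the hyaluronan receptor gene named in the series title for hepatocytes, stood at 48.2 CPM and 46.9 CPM in these T cells, with S1pr1 and Gpr183 (0.28) above and Hmmr (-0.68) and Spp1 (-0.57) below, and the list median was 0.010 under equal cluster weights. Antigen receptor response genes were centred near 0, with a median of -0.001 (12 of 25 higher, percentile 59.2), with Irf8 (0.51) and Dusp2 (0.37) above and Tagap (-0.41) and Icos (-0.37) below. This median ran from -0.194 without cycling-like clusters to 0.086 over genes with a mean of at least 20 CPM, and the early activation gene Cd69 stood at 25.6 and 24.1 CPM.

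Cell cycle genes were lower in the old-recipient library. Of 52 measured G2/M genes, 46 were lower and 6 higher, with 4 at least 1.5-fold lower with the pseudocount and a median of -0.28 (-0.32 to -0.25, percentile 0.00). Mki67, a marker of dividing cells, stood at 225 CPM in the young-recipient library and 165 CPM in the old-recipient library, 1.36-fold lower (1.32 to 1.40). Hmmr (44.7 and 27.6 CPM) and Ckap2l (38.8 and 25.6 CPM) were among the lower examples, and Hjurp (0.047) and Ccnb2 (0.036) were level. Of 41 measured S phase genes, 38 were lower (median -0.14, percentile 0.00), with Ccne2 at -0.40 and Pola1 at -0.40, and Pold3 at 0.098 and Clspn at 0.014. Without the cycling-like clusters the medians changed sign, to 0.13 for G2/M and 0.12 for S phase, with Hmmr at -0.055, Ccne2 at 0.41 and Clspn at 0.64, and with equal cluster weights the G2/M median was -0.097 and the S phase median -0.009.

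Glycolysis genes were higher and mitochondrially encoded genes lower in the old-recipient library, in every large cluster. Of 23 measured glycolysis and glucose uptake genes, 21 were higher (median 0.23, 0.20 to 0.26, percentile 100), with cluster medians of 0.16 to 0.56. The lactate exporter gene Slc16a3 stood at 20.5 and 31.3 CPM and the glycolytic enzyme gene Tpi1 at 104 and 149 CPM, while Eno3 (-0.36) and Pgam1 (-0.14) were lower. All 13 mitochondrially encoded genes were lower (median -0.29, percentile 0.00), with mt-Nd2 at 709 and 540 CPM and mt-Atp8 at 503 and 382 CPM, and cluster medians of -0.32 to -0.16. The median mitochondrial share of UMIs per cell was 0.98% and 0.83% in young and old recipients. Nuclear genes of oxidative phosphorylation had a median of -0.049 (28 of 78 higher, percentile 1.11), with Atp5b (0.42) and Atp5md (0.35) above and Ndufb11 (-0.55) and Cox5a (-0.42) below.

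Apoptosis and p53 response genes were lower in the old-recipient library, with 14 of 23 lower and a median of -0.15 (percentile 0.06). Bax (-0.74) and Sesn1 (-0.28) were its lowest well-measured genes, and Gadd45b (0.39) and Aen (0.24) its highest. Cytosolic ribosomal protein genes were evenly split, with 38 of 80 higher (median -0.007, percentile 38.8), but single members lay far apart. Rps27 stood at 3099 and 5574 CPM and Rpl35a at 2558 and 3735 CPM, while Rpl9 stood at 461 and 270 CPM and Rpl7 at 504 and 348 CPM. Some of these genes have near-identical copies whose reads the counting could divide, so their values are uncertain. The other lists given next lay within the middle 95% of random lists in the main comparison, though glucocorticoid response genes reached -0.154 over genes with a mean of at least 20 CPM. Fatty acid oxidation had a median of -0.042 (percentile 21.7; Ppard 0.25, Eci2 0.19, Acsl5 -0.38, Fabp5 -0.16). Cholesterol and fatty acid synthesis had 0.018 (percentile 78.0; Scd2 0.24, Srebf2 0.063, Acaca -0.020), and the amino acid and unfolded protein responses 0.012 (percentile 70.9; Ddit3 0.26, Xbp1 0.24, Ddit4 -0.31, Phgdh -0.15). Heat shock and dissociation stress genes had 0.020 (percentile 73.3; Hspa8 0.67, Jun 0.59, Hsph1 -0.41, Hspe1 -0.40). Glucocorticoid response genes had -0.024 (percentile 42.8; Fkbp5 0.20, Zfp36l2 -0.22), and antioxidant and iron genes 0.017 (percentile 72.7; Gsr 0.26, Txnrd1 0.13, Sod1 -0.42, Prdx1 -0.41).

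**Figure D3:**
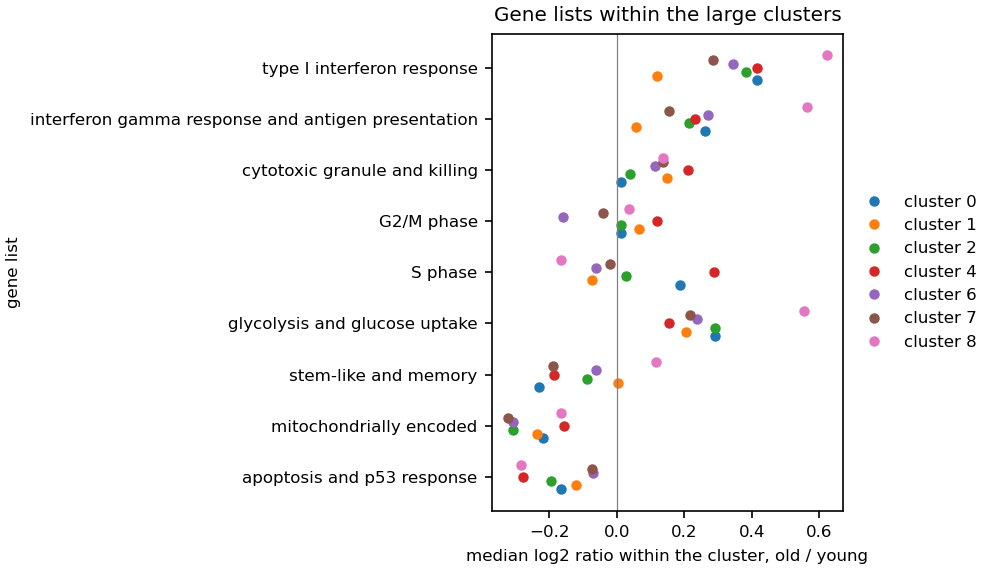
Median log2 ratio (old-recipient over young-recipient) of 9 gene lists within each of the 7 clusters with at least 90 cells in both libraries, 1 point per cluster. The type I interferon list lies above 0 in each cluster, from 0.12 to 0.62, while the G2/M list lies on both sides, from -0.16 to 0.12.

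Clustering of the gated cells gave 10 clusters. Cluster 8 was led by Gzma, Ccl5, Gzmb, Gzmm, Slfn8 and Slfn5 and is called granzyme-high here. It held 2.48% of young-recipient cells (2.02 to 3.02%) and 8.68% of old-recipient cells (7.91 to 9.49%). Because its leading genes differ between the libraries, cells were clustered again without genes at least 1.5-fold apart, its leading genes and the cytotoxic, cytokine, terminal effector and interferon lists. The matching cluster then held 1.51% (1.15 to 1.94%) and 3.67% (3.16 to 4.23%), and it contained 44.0% of the granzyme-high cells. Cluster 0, led by Sox4, Maf, Kcnc1, Eomes and Il10ra, held 8.67% (7.81 to 9.60%) and 17.0% (16.0 to 18.1%). Its counterpart without those genes contained 92.3% of its cells and held 9.49% (8.59 to 10.4%) and 18.3% (17.3 to 19.4%). Cluster 4, led by Trmt61a, D030028A08Rik, Pus7 and Srm, with Myc and Gnl3 also among its 10 leading genes, held 17.3% and 12.8%. Its counterpart held 24.2% and 17.8%.

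The granzyme-high cluster held 97 young-recipient and 433 old-recipient cells, so its young-recipient values rest on few cells. Inside it, Gzmb stood at 273 and 330 CPM (log2 ratio 0.27), while Gzma (361 and 180 CPM), Ccl5 (6328 and 3142 CPM) and Havcr2 (78.6 and 42.1 CPM) were lower per UMI in the old-recipient library. Clusters 6 and 7, led by G2/M genes such as Cdc20 and Ccnb2 and by histone genes, were cycling-like. Together they held 24.0% of young-recipient cells (22.7 to 25.4%) and 18.5% of old-recipient cells (17.5 to 19.6%), and 23.5% and 17.3% when cell cycle genes were left out of the clustering. The low-depth cluster 3, kept out of this class by a threshold set after the data were seen, held 1.66% and 1.04%. Cluster 5, led by Fosb, Fos, Nr4a3 and Egr3, was recently stimulated-like and held 1.94% and 1.74%. Cluster 1, led by Il7r and Pik3ip1, held 10.6% and 10.9%, and cluster 2, led by Spock2 and Il18r1, held 33.1% and 28.9%. Sizes of these last 3 clusters are given without direction.

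Shares of cells with a UMI were compared after thinning each cell to 4000 UMIs, which left out 152 young-recipient and 368 old-recipient cells. A Gzmb UMI was found in 2.02% of young-recipient cells (1.60 to 2.52%) and 4.87% of old-recipient cells (4.27 to 5.53%), against 4.17% and 7.74% unthinned. In cluster 1, with median depths of 6532 and 5654 UMIs, the thinned shares were 0.0% and 0.85%. Gzmk UMIs were found in 0.77% and 3.83% of thinned cells (2.17% and 7.42% unthinned), Gzma in 0.75% and 1.69% (1.46% and 3.35% unthinned) and Prf1 in 17.1% and 24.3% (34.6% and 39.8% unthinned). In cluster 1 these thinned shares were 1.29% and 2.34% for Gzmk, 0.52% and 0.21% for Gzma, and 14.7% and 20% for Prf1. Cluster 1 held Gzmk at 3.29 and 5.33 CPM and Prf1 at 36.5 and 54.2 CPM, so it is no reference without these genes. Mki67 UMIs were found in 23.04% (21.7 to 24.4%) and 17.9% (16.8 to 19.1%), and Il7r UMIs in 8.22% and 5.09%, against 31.3% and 24.5%, and 13.04% and 8.20%, unthinned. Pdcd1 was found in 13.8% (12.7 to 14.9%) and 12.6% (11.6 to 13.5%), Cd44 in 17.8% and 18.7%, and Cd69 in 9.87% and 9.63%, with overlapping intervals. Tox was found in 86.2% and 87.1%, Tcf7 in 82.2% and 81.0%, and Lag3 in 68.1% and 70.0%. Ifng was found in 2.71% and 2.77%, Tnf in 5.59% and 4.70%, Klrg1 in 0.21% and 0.26%, Cxcr6 in 0.35% and 1.19%, and Havcr2 in 0.59% and 1.39%. The median number of genes per thinned cell was 1511 and 1499.

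**Figure D4:**
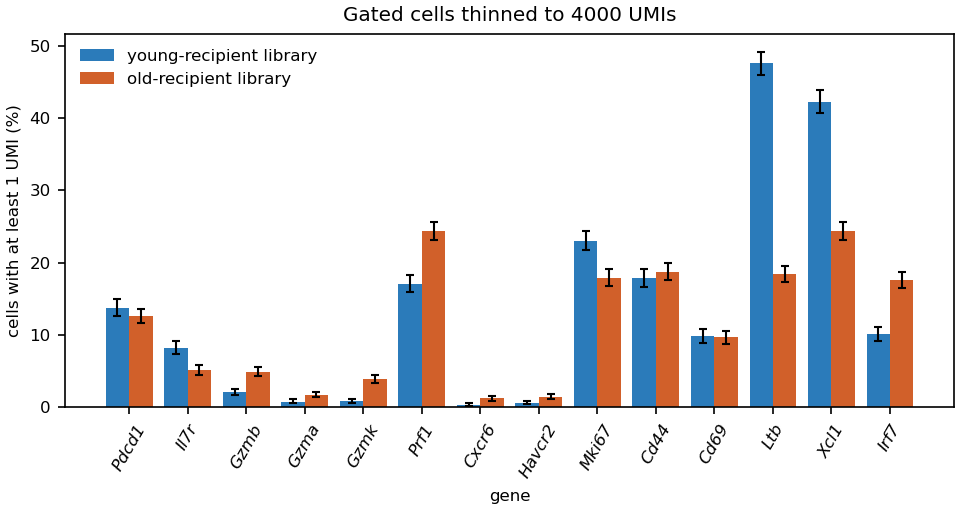
Share of gated cells with at least 1 UMI of each gene (%) after thinning to 4000 UMIs, for the young-recipient library (blue) and the old-recipient library (orange), with exact 95% binomial intervals. Gzmb lies at 2.02% and 4.87% and Mki67 at 23.04% and 17.9%, while Pdcd1 lies at 13.8% and 12.6%.

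The CD8 T cell identity list had 10 of 20 genes higher (median 0.015, percentile 68.9), with Cd2 (0.54) and Lat (0.25) above and Cd3g (-0.26) and Trbc1 (-0.22) below. Cd8b1 stood at 1077 CPM in the young-recipient library and 1134 CPM in the old-recipient library. Cluster 9, led by the myeloid genes Lyz2, Tyrobp, Spi1 and Csf1r, held 8 young-recipient and 18 old-recipient cells, or 0.205% (0.0884 to 0.403%) and 0.361% (0.214 to 0.570%). Lyz2 stood at 1.07 and 3.79 CPM over all gated cells, 3.53-fold higher in the old-recipient library (2.55 to 4.98). That interval counts UMIs and not cells, and Lyz2 stood at 624 CPM in cluster 9 against 0.10 CPM in the other cells. By cell, a Lyz2 UMI was found in 0.28% (0.14 to 0.50%) and 0.40% (0.25 to 0.62%) unthinned, with overlapping intervals. The hepatocyte gene Alb stood at 0.14 and 0.15 CPM, from 6 and 7 cells. Summed over each marker list, hepatocyte genes gave 10.2 and 13.4 CPM, Kupffer cell and macrophage genes 12.7 and 16.6 CPM, neutrophil genes 0.53 and 0.84 CPM, and erythroid and platelet genes 0.48 and 0.41 CPM. In the hepatocyte sum, Apoe gave 4.20 and 6.02 CPM and Hp 0.091 and 2.48 CPM, and both also lead cluster 9. B and plasma cell genes gave 189 and 194 CPM, nearly all from Ighm (180.1 and 187 CPM), and endothelial genes 143 and 146 CPM, nearly all from Pecam1 (136 and 139 CPM), which T cells also transcribe. NK and ILC1 genes gave 66.2 and 77.8 CPM, with Txk at 38.5 and 50.1 CPM. Stellate cell and fibroblast genes gave 4.52 and 4.37 CPM, and cholangiocyte genes 42.8 and 37.1 CPM, of which Spp1 gave 26.3 and 17.4 CPM. The CD4 and regulatory T cell list had a median of -0.017 (percentile 51.8; Izumo1r 0.15). The gamma-delta list summed to 32.9 and 44.6 CPM, with Trdc at 26.3 and 26.4 CPM and the gamma chain segment Trgv2 at 3.68 and 14.03 CPM.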

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

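The comparison outside the gate used marker lists fixed before the data were examined, while its minimum of 50 UMIs was set after the data were seen. Cells that passed the filters but lacked a Cd8 or Cd3 UMI, 154 in the young-recipient library and 207 in the old-recipient library, take part only in the alternatives without the gate. Relative to the young-recipient library as the control level, 4 marker lists that met this minimum had more signal in those old-recipient cells. Monocyte and dendritic cell genes gave 3114 CPM against 1023 CPM, 3.04-fold higher (counting interval 2.75 to 3.38). Hepatocyte genes gave 518 CPM against 134 CPM, of which Apoe, also a leading gene of myeloid cluster 9, gave 355 CPM against 111 CPM. Kupffer cell and macrophage genes gave 202 CPM against 18.5 CPM. NK and ILC1 genes, a list that includes Tyrobp, another leading gene of cluster 9, gave 566 CPM against 397 CPM. Its member Ncr1 went the other way, at 2.66 CPM against 11.5 CPM, from 2 and 5 UMIs. Neutrophil genes, under the minimum of 50 UMIs, were also higher in old recipients, at 29.3 CPM against 4.62 CPM, from 22 and 2 UMIs. Liver endothelial genes went the other way, at 288 CPM against 383 CPM, a fold of 0.75 (0.61 to 0.92). Among single genes, Lyz2 gave 202 CPM against 20.8 CPM and Cd74 1420.4 CPM against 524 CPM. Inside the gate the same 4 lists summed to 201 and 178, 13.4 and 10.2, 16.6 and 12.7, and 77.8 and 66.2 CPM in old and young recipients. The sort was on Thy1.1 and CD8, yet barcodes with these markers were in both libraries. T cell transcripts were present outside the gate too, with Cd3e at 867 CPM against 718 CPM (1141 and 1016 CPM inside the gate). The intervals here count UMIs and not cells, and no explanation was tested.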

How the results depend on the processing

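All alternatives were fixed before the data were examined except 3: without cells above the 95th percentile of UMIs, without clusters 3, 8 and 9, and clustering without differing genes. The type I interferon, interferon gamma and cytotoxic medians stayed above 0 under all 15 alternatives, with ranges of 0.31 to 0.63, 0.18 to 0.47 and 0.071 to 0.30. Of 37 named genes at least 1.5-fold apart with the pseudocount, 35 kept their direction under all alternatives run on them (13, or 12 for ribosomal protein genes). Gzma (-0.274) and Ccl5 (-0.345) reversed under equal cluster weights, where the rare Klrg1, not 1.5-fold apart on that scale, was at -0.495. These weighted values rest largely on the 97 young-recipient cells of the granzyme-high cluster. Equal cluster weights also gave -0.009 for the terminal effector list, -0.002 for the costimulation and cytokine receptor list, 53 genes at least 1.5-fold higher, and medians of 0.071 (cytotoxic), 0.32 (type I interferon) and -0.097 (G2/M). Without cycling-like clusters, the G2/M median was 0.13 and the S phase median 0.12, which by construction removes the cells richest in those genes. A pseudocount of 5 CPM gave 58 genes higher and 27 lower, and medians of 0.44 (type I), 0.30 (gamma) and -0.25 (G2/M). A mean of at least 20 CPM gave 42 and 21 genes, and medians of 0.083 (cytotoxic), 0.47 (type I) and 0.24 (gamma), with fewer genes entering. No filter on low values gave 197 and 108 genes and a type I median of 0.63. Without cells above the 95th percentile of UMIs, the type I median was 0.60 and the G2/M median -0.37. Without clusters 3, 8 and 9 the medians were 0.11 (cytotoxic), 0.31 (type I), 0.18 (gamma) and -0.23 (G2/M). The cycling-like share was 18.8% in young and 13.7% in old recipients at resolution 1.0, 25.7% and 20.2% with differing genes left out, and 17.3% in old recipients with cell cycle genes left out. With differing genes left out, shares in young and old recipients were 24.2% and 17.8% for cluster 4 and 1.51% and 3.67% for cluster 8, and 18.3% of old-recipient cells for cluster 0. Values for median UMIs per cell, young recipients, and median UMIs per cell, old recipients, were 8096 and 6962 with no cell filter, and 8361.5 and 7183.5 without the Cd8 and Cd3 gate. Median and mean differed in sign for the antigen receptor (mean 0.034), amino acid (mean -0.002) and CD4 T cell (mean 0.001) lists. Except where stated, the cause was not tested. TMM factors, 1.003 and 0.997, moved 2 list medians beyond their counting interval, to -0.04 for nuclear oxidative phosphorylation and 0.002 for ribosomal proteins. No paired analysis was possible because each group had 1 library. Lower depth per cell in the old-recipient library limits its unthinned shares of cells with a UMI. Summed CPM are scaled to the library total, but cells with more UMIs weigh more in them, and depth differed unevenly between clusters. Median UMIs in young and old recipients were 22613 and 19576.5 in cluster 7, but 6242 and 6421 in cluster 8.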

Other observations

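Tests on the share of the granzyme-high cluster, on GC content and length, on genes with a named copy, on the whole cytotoxic list among Trbv13-3 cells and on thinned shares over the G2/M list were written after the results they measure had been seen, and the other tests before. Genes outside the rule, chosen after their values were seen, also lay apart. Maf, a transcription factor that leads cluster 0, stood at 7.92 CPM in the young-recipient library and 25.3 CPM in the old-recipient library, and the metallothionein gene Mt1 at 5.71 and 24.3 CPM. Interferon-induced genes below the measured level were higher as well, with Isg15 at 1.05 and 5.48 CPM and Ifit1 at 0.53 and 3.47 CPM. The pro-apoptotic genes Bak1 (22.0 and 12.3 CPM) and Bbc3 (6.69 and 3.58 CPM) were lower beside Bax. Y-linked genes were slightly lower, within the range of random lists (0 of 4 higher, median -0.098, counting interval -0.163 to -0.011, percentile 14.3, with Uty at -0.048 and Eif2s3y at -0.16), and Xist had 2 and 0 UMIs in young and old recipients.

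The P14 receptor uses the beta chain segment Trbv13-3. It gave 60.7% of 694 Trbv UMIs in the young-recipient library (56.9 to 64.3%) and 68.3% of 1063 in the old-recipient library (65.4 to 71.1%). In the granzyme-high cluster it gave 32.0% of 25 UMIs (14.9 to 53.5%) and 52.1% of 117 UMIs (42.7 to 61.5%), and in the other gated cells 61.7% and 70.3%. The alpha chain segment Trav14 of that receptor gave 28.7% of 1014 Trav UMIs and 32.1% of 1225, and 16.2% and 33.7% in the granzyme-high cluster. Unspliced or germline transcripts and those of host cells were not separated in these counts.

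Interferon response and cytotoxic genes were higher in the old-recipient library. With equal cluster weights the type I interferon median was 0.32, still above the random lists, so a larger granzyme-high cluster is not the whole of the interferon part. For the cytotoxic part that cause cannot be told apart: Gzmb, Gzma, Gzmk and Prf1, tested first, had a median of 0.86 but are among the highest genes of the list, and the whole list, tested after that result, was at 0.071 (counting interval 0.009 to 0.11), spanning 0.059, the upper end of random lists. The interferon median was 0.72 among the 368 and 582 cells with a Trbv13-3 UMI and no other Trbv UMI. This argues against host T cells that passed the sort as its whole source, as far as that UMI marks P14 cells. Transcripts of host cells were not separated, so a part from them is not excluded. For the cytotoxic part host T cells remain open. Gzmb was 2.37-fold higher (1.70 to 3.36) in these cells, past the bound of 1.5 written before. That interval counts UMIs, 47 and 154 in young and old recipients, and not cells, so it does not decide the question. Gzmb also has the highest log2 ratio of the list in the main comparison. The whole list was at 0.157 (0.052 to 0.303), spanning the upper end of random lists at 0.121. The age of the recipient, or another difference between the pools, remains open and untested.

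Some ribosomal protein genes and Ltb were shifted by like amounts in all 7 large clusters, with Rps27 at 0.75 to 0.92, Rpl9 at -0.81 to -0.69 and Ltb at -1.95 to -1.34 on the log2 scale. Across 8530 measured genes the log2 ratio hardly followed 3' GC content (Spearman rho 0.076) or length (0.05). Subtracting the median of genes of like GC and length could thus hardly move genes chosen for an absolute log2 ratio of at least 0.4. This subtraction therefore decides nothing on GC content and length for these genes. The median absolute log2 ratio of 9 such genes was 0.53 before it and 0.588 (counting interval 0.578 to 0.599) after it. Under the bound written first, a log2 ratio of 0.58, this was undecided because the interval reached below it, and 8 genes of a higher minimum size, tried first, gave 0.603 with no interval; both the genes and the bound were reset after these values were seen, the bound to 0.9 of the value before, because 0.58 lay above that value. Summing with genes of the same stem left 0.494 against 0.52 over 8 ribosomal genes, which decides nothing for the 4 without such a gene, and 0.629 against 0.651 over the 4 with one, which argues against reads moving between named copies, except for Rpl36a, whose log2 ratio went from 0.49 to 0.27. Copies absent from the counted genes, a difference in library preparation and the age of the recipient cannot be separated with 1 library per age.

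G2/M genes were lower in the old-recipient library. Fewer cycling-like cells were predicted to leave no difference under equal cluster weights. There the median was -0.097 (counting interval -0.13 to -0.079, below the random lists), against -0.28 in the main comparison, so most of it went with the cluster shares. These weights equalise cell numbers and not UMIs per cell. Median UMIs in young and old recipients were 16140 and 13532 in cluster 6, and 22613 and 19576.5 in cluster 7. What remained therefore decides nothing on a difference beyond the cluster shares. Within the large clusters the G2/M median ran from -0.16 to 0.12. For lower depth per cell single genes differed after thinning, with Mki67 UMIs in 17.9% of old-recipient and 23.04% of young-recipient cells but Top2a in 38.0% and 38.2% and Ccnb1 in 2.81% and 3.81%, with overlapping intervals for the latter pair of genes. Over all 52 genes the thinned share was lower in old recipients for 46, with a median log2 ratio of shares of -0.273 (-0.303 to -0.226), below the random lists, which argues against depth as the whole cause. A lower rate of division in old recipients, as a hypothesis, remains untested. Free RNA and the pooling of mice were also not assessed.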
